A study of Phaeodactylum tricornutum with 21 samples.

How the data were processed

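Cells of the wild-type strain CCAP 1055 of the marine diatom Phaeodactylum tricornutum, a unicellular alga that stores laminarin, a beta-glucan, were grown in days of 12 h light and 12 h dark. Per the labels, RNA was taken at 7 time points, 4 h apart, from 0 h to 24 h, with 3 libraries at each, 21 in all. RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with an Illumina TruSeq kit, per the labels' protocols. The labels place 0, 4, 8 and 12 h in the light period and 16, 20 and 24 h in the dark period. They do not say whether the libraries of a time point came from separate cultures, so p-values here measure the spread between these samples, which may be technical. Each sample was placed in its group by the time given in its labels, and all 21 columns of the table matched a sample title.

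The authors deposited one table of FPKM values, reads scaled by feature length and library size, with 12693 rows and 21 columns, named FPKM per the file headers. CASAVA 1.7 is named in the submitters' processing notes. The aligner, the read counter, the genome build and the gene annotation are not given in the sources used here. From the values alone, FPKM in each library was a whole number of reads divided by the feature length and by a library factor. Up to a multiplier common to all libraries, the recovered factors matched median-of-ratios size factors, with a largest relative difference of 1.9e-11. The common multiplier was taken as the geometric mean of the library totals, which rests on the implied lengths, given below, coming out whole. Whole reads were recovered for all 11825 rows with a value above 0. Of the values above 0, 99.62% came out whole within 0.01 of a read, and 868 rows were 0 in every library. The recovery was tested on simulated reads for 11782 rows, of which 99.414% came back exactly and 100% up to a divisor common to the row. Recovered totals ran from 16470751 to 19458547 reads per library, so at this depth single reads were resolved even in features with an FPKM under 1. The length implied for each feature was a whole number of bases in 99.77% of rows, had a median of 1248 bases, and was a multiple of 3 in 88.2% of rows. Because the size factors set the median feature level, a scale based on total reads was tried as an alternative.

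The row labels were not used as gene names. Only the labels of rows 1 and 2 stand outside a run of numbers that begins at row 3, after which each label is the one before plus 1, for 12690 steps, while 99.73% of adjacent rows stand in descending order of reads summed over libraries. Of the label numbers, 515 occur among the 10022 numbered locus tags of the RefSeq table used for comparison, and 6664 lie above its highest number. Over the 515 features, implied length and RefSeq gene length were unrelated, with a Spearman rho of −0.043 (permutation p = 0.33, two-sided, 10000 permutations, features not being independent replicates). Features are therefore named by their row number in the table. The 22 gene lists fixed before the data were examined, laminarin synthesis and breakdown among them, and the list tests planned on them, were not run, because no row could be assigned to a gene.

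Features with an FPKM of at least 1 in at least 3 libraries were tested, 11168 in number. The test was limma 3.58.1 (R 4.3.3, with statmod 1.5.0), with trended and robust moderation, on log2(FPKM + 1), with 1 mean per time point fitted over all 21 libraries. Values were adjusted by Benjamini-Hochberg over features, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of features with low values. A 6-contrast F test asked which features differed between any time points. The 8 comparisons were the mean of the light period against the mean of the dark period, each time point weighted equally, the 6 successive pairs of time points, and 24 h against 0 h. For each feature past the F test, the time of its highest mean log2 level was recorded. These tests, the rule for named features and most alternatives were fixed before the data were examined. The rule, for a table without usable annotation, names the 2 features with the highest and the 2 with the lowest log2 fold change of each comparison among those past the threshold and with a mean level at or above the median of tested features. Rows 1 to 3 are named in addition because of their labels and were chosen after their values were seen, as were row 3231's course and the features counted as confined to a single time point. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the recovery and the plots.

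The limma steps were tested on simulated reads for 4 h against 0 h, with 200 of 11138 features changed. Of those changed by 0.5, 1 and 2 on the log2 scale, 34.8%, 91% and 100% were called, and 9 of 160 calls were false. In the real comparison 59.8% of features changed, which loosens the adjusted threshold, and the simulated noise was independent between features. These shares therefore do not carry over to the real calls. Alternatives covered normalization (quantile, median of features, library totals), the low-value filter, the pseudocount of 0.1, the size threshold, the replicate number as a block, each library left out in turn, the choice of time points for the light and dark periods, voom weights on the recovered reads, and removal of each library's length trend (lowess, span 0.3). Voom, the library totals, the length trend, 2 alternatives that leave out libraries or time points, and quantile normalization for the time of highest level were chosen after seeing the data. Over the 21 pairs of libraries of the same time point, the median chi-square of a feature's reads ranged from 2.61 to 13.95, where sampling noise alone gives 0.45, so no pair looked like 1 library deposited more than once. This does not show that the libraries came from separate cultures.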

Results

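RNA levels were followed in wild-type Phaeodactylum tricornutum through 1 cycle of 12 h light and 12 h dark, in a series whose title concerns the daily rise and fall of laminarin, the diatom's storage glucan. Each of the 7 time points had 3 libraries, with recovered totals of 16470751 to 19458547 reads. Features are given by their row in the table, since the row labels did not identify genes. Levels are FPKM as mean ± SD with n = 3 libraries, and log2 fold changes come from limma on log2(FPKM + 1) with their SE.

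Which transcripts moved at any time of the cycle was the first question. Of 11168 features tested, 10184 (91.2%) differed between time points, and 984 did not pass the threshold. The range from lowest to highest mean had a median of 1.26 on the log2 scale, or 2.39-fold, against a median SD within time points of 0.21. Among changed features, 7054 had a range of at least 2-fold, 2817 of at least 4-fold and 641 of at least 16-fold. In 3289 features (29.5%) the 3 libraries with the highest values all came from 1 time point, where chance gives 0.53%. The widest range among the named features was that of row 59, which went from 0.305 ± 0.127 FPKM at 8 h to 4379 ± 1210 at 24 h. Libraries of a time point correlated at 0.965 to 0.991 over features, and libraries of different time points at 0.583 to 0.958. The lowest correlations lay between 0 h and 12 h. On the first 2 principal components, with 55.2% and 22% of the variance, the time points lay on a loop in the order of sampling.

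**Figure D1:**
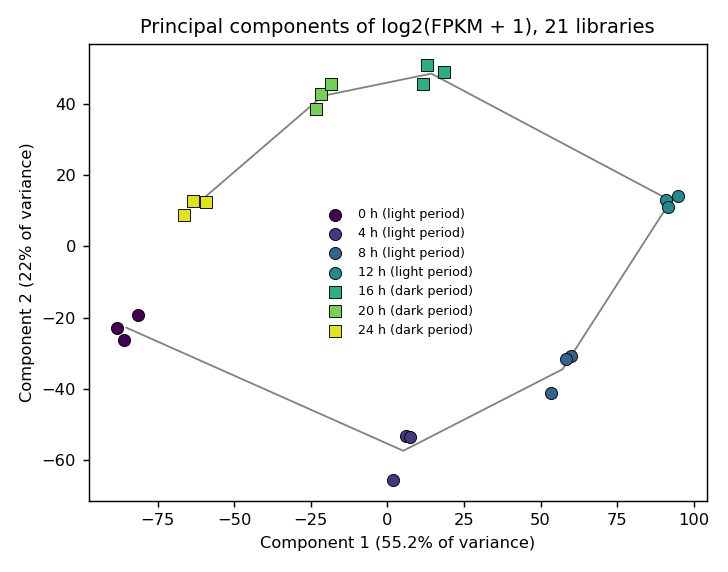
Positions of the 21 libraries on principal components 1 (55.2% of variance) and 2 (22%) of log2(FPKM + 1), in component units. Points are libraries, circles the light period and squares the dark period as labelled, and the line joins the means of successive time points, with 0 h and 12 h at opposite ends of component 1.

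On the deposited scale, features at their highest level at 0 h or at 12 h were the most numerous. Of the 10184 changed features, 2492 (24.5%) were highest at 0 h and 2530 (24.8%) at 12 h. A further 1362 were highest at 24 h, 1275 at 8 h, 1037 at 4 h, 801 at 16 h and 687 at 20 h. In all, 62.7% were highest at 0, 12 or 24 h, with an SD of 2.5 percentage points when each replicate number was used alone. With library totals as the scale the share was 44.3%, with 1390 features highest at 0 h, 2069 at 4 h, 1391 at 8 h, 1929 at 12 h, 956 at 16 h, 1365 at 20 h and 1276 at 24 h, so 4 h came first and 16 h last. That share is near what an even spread over the 7 time points would give. Of the features highest at 0 h, 1233 were lowest at 12 h, with a median range of 1.82 on the log2 scale, and 586 were lowest at 8 h. The reverse course, highest at 12 h and lowest at 0 h, held for 1158 features with a median range of 1.88. Features highest at 0 h took 47.5% ± 1.5 of all reads at 0 h and 16.1% at 12 h. Those highest at 12 h took 43.6% ± 2.2 at 12 h and 13.3% at 0 h. These shares belong to features chosen by their highest time, so their own time is high by construction. The 10 most abundant features took 6.13% ± 0.61 of reads at 0 h, 3.18% ± 0.36 at 4 h, 2.95% ± 0.36 at 8 h and 4.08% ± 0.33 at 12 h. In the dark they took 4.23% ± 0.99 at 16 h, 3.96% ± 0.14 at 20 h and 5.32% ± 0.2 at 24 h.

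**Figure D2:**
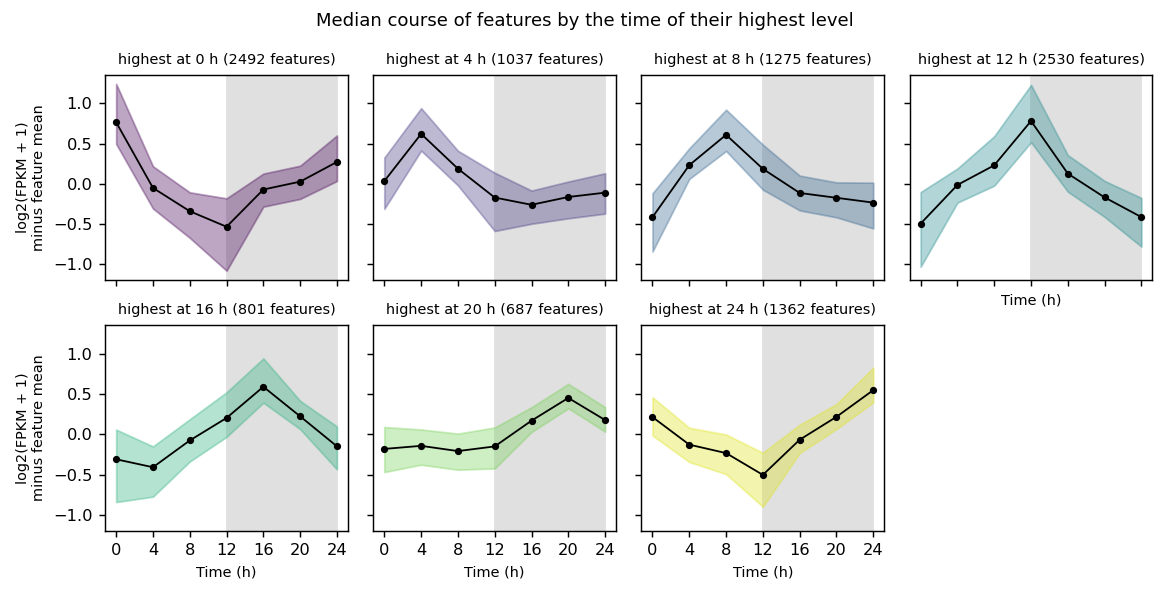
Median log2(FPKM + 1) minus each feature's mean over time points (y axis) against time in h (x axis), for changed features grouped by the time of their highest mean. Lines are medians, shaded bands the middle 50% of features and grey the dark period; panels hold 687 to 2530 features, and each rises at its own time by construction.

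Light and dark periods were compared as the mean of 4 and of 3 time points. Rows 649 and 139 were the named features higher in the light, by 5.54 (SE 0.17) and 5.50 (SE 0.24) on the log2 scale. Row 649 stood at 1425 ± 576 FPKM at 4 h and 2.86 ± 1.72 at 16 h, and at 96.3 ± 24.1 at 24 h. Row 139 went from 3340 ± 2090 FPKM at 4 h to 13.2 ± 4.71 at 20 h. Rows 12 and 163 were higher in the dark, with log2 fold changes of −6.45 (SE 0.33) and −6.0 (SE 0.08). Row 163 fell from 557 ± 50.3 FPKM at 0 h to 0.137 ± 0.0489 at 8 h, when each library held 3 to 6 of its reads, and stood at 558 ± 69.0 at 16 h. Row 12 held 7.99 ± 2.19 FPKM at 4 h and 3659 ± 342 at 20 h. In this comparison 6956 features (62.3%) changed, 3416 higher and 3540 lower in the light, and 613 and 522 of them by at least 2-fold. The light mean includes 0 h, so the comparison is not a plain response to light. Libraries of 0 h had mean correlations of 0.927 with 24 h, 0.848 with 20 h and 0.779 with 16 h. With the other light time points these were 0.830 at 4 h, 0.701 at 8 h and 0.595 at 12 h. Without 0 h, 7751 features changed. Library totals as the scale gave 2931 higher and 3986 lower. Other divisions of the 7 time points into 4 and 3 gave as many changed features or more in 8 of 34 cases. Each of those 8 kept 0 h and 24 h on the same side, whereas the labels separate them.

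Between 0 h and 4 h the greatest number of features moved of any successive pair. Both are labelled light period, but the labels do not say whether 0 h was sampled before or after the light came on, so this step can include the change from dark to light. Row 59 fell from 3745 ± 307 FPKM to 0.465 ± 0.0243, a log2 fold change of −11.32 (SE 0.15), and its reads went from at least 59943 per library to at most 12. Row 1255 fell from 1998 ± 219 to 2.26 ± 0.74 FPKM, or −9.28 (SE 0.23). Row 610 rose from 27.5 ± 12.9 to 911 ± 325 FPKM, by 5.08 (SE 0.41), and row 60 from 9.93 ± 1.7 to 277 ± 37.3, by 4.67 (SE 0.14). In all 6676 features changed, 3339 higher and 3337 lower at 4 h, of which 1516 and 1375 by at least 2-fold. Library totals as the scale raised the median feature by 0.36 on the log2 scale and gave 5309 higher and 1921 lower. The 4 named features changed by far more than that shift, so their directions could not reverse on that scale.

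Through the later hours of light, changes were fewer from 4 h to 8 h and more numerous again from 8 h to 12 h. Row 276 rose from 13.4 ± 3.16 FPKM at 4 h to 472 ± 88.5 at 8 h and 2849 ± 480 at 12 h, the first step being 5.05 (SE 0.19). Row 123 rose by 3.68 (SE 0.13) from 4 h to 8 h. Row 39 fell from 301 ± 45.3 to 11.2 ± 1.53 FPKM over the same hours, or −4.63 (SE 0.34), and row 1675 from 121 ± 12.8 to 5.39 ± 1.81, or −4.29 (SE 0.21). From 8 h to 12 h row 18 rose from 2.34 ± 0.284 to 322 ± 34.8 FPKM, by 6.59 (SE 0.14), and row 245 from 9.31 ± 2.80 to 320.5 ± 97.2, by 4.96 (SE 0.22). Both went on to higher levels at 16 h, with 1570 ± 63.5 FPKM for row 18 and 2024 ± 250 for row 245. Row 248 fell from 2432 ± 796 to 114 ± 42.4 FPKM, or −4.42 (SE 0.42), and row 5462 from 311 ± 125 to 13.1 ± 3.20, or −4.39 (SE 0.38). From 4 h to 8 h 3779 features changed, 1918 higher and 1861 lower, and from 8 h to 12 h 5167 changed, 2614 higher and 2553 lower. Of the latter, 571 rose and 884 fell by at least 2-fold. By at least 4-fold, 113 rose and 159 fell in the first step and 54 rose and 206 fell in the second. The second step thus had no excess of large changes. Fitted on only the 6 libraries of each pair, the counts were closer, at 4559 and 4873. With library totals the splits were 1444 higher and 2431 lower for the first step and 1817 higher and 3315 lower for the second.

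Light gave way to dark between 12 h and 16 h, and both named features that fell had built up through the day. Row 41 had risen from 33.8 ± 4.98 FPKM at 0 h to 5897 ± 1410 at 12 h and stood at 40.6 ± 7.64 at 16 h, a log2 fold change of −7.13 (SE 0.21). Row 110 went from 2955 ± 261 to 13.5 ± 1.02 FPKM, or −7.67 (SE 0.21). Row 163 rose from 2.56 ± 0.464 to 558 ± 69.0 FPKM, by 7.30 (SE 0.15), and row 133 from 0.588 ± 0.171 to 170 ± 26.7, by 6.75 (SE 0.14). Of 5494 changed features, 2856 were higher and 2638 lower at 16 h, and 1086 and 890 of them by at least 2-fold. Library totals gave 3529 higher and 2024 lower.

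Fewest features moved between 16 h and 20 h, both in the dark. Row 2455 rose from 7.35 ± 2.23 to 186 ± 71.7 FPKM, by 4.44 (SE 0.29), and row 1255 from 14.8 ± 1.72 to 243 ± 9.08, by 3.95 (SE 0.23). Row 457 fell from 40.8 ± 14.5 to 6.93 ± 2.17 FPKM, or −2.39 (SE 0.23), and row 3440 from 120.5 ± 24.0 to 25.3 ± 2.16, or −2.19 (SE 0.29). In this step 2449 features changed, 1069 higher and 1380 lower, and 201 rose and 427 fell by at least 2-fold. By at least 4-fold, 31 rose and 14 fell. Without library 1 of 20 h the count was 1606, and with library totals the split was 1343 higher and 1094 lower. From 20 h to 24 h 3302 features changed, 1613 higher and 1689 lower. Row 2357 rose over these hours from 13.6 ± 3.35 to 520 ± 158 FPKM, by 5.13 (SE 0.20), and row 3231 from 6.91 ± 2.50 to 273 ± 76.3, also by 5.13 (SE 0.24). Row 669 fell from 72.3 ± 30.4 to 11.3 ± 1.93 FPKM, or −2.51 (SE 0.25), and row 2553 from 35.4 ± 2.34 to 6.37 ± 1.84, or −2.33 (SE 0.22). Changes of at least 2-fold between 20 h and 24 h were near even, with 490 features higher and 482 lower. Those of at least 4-fold were mostly rises, with 103 features higher and 14 lower. With library totals as the scale the split of all changes was 1079 higher and 2391 lower.

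**Figure D3:**
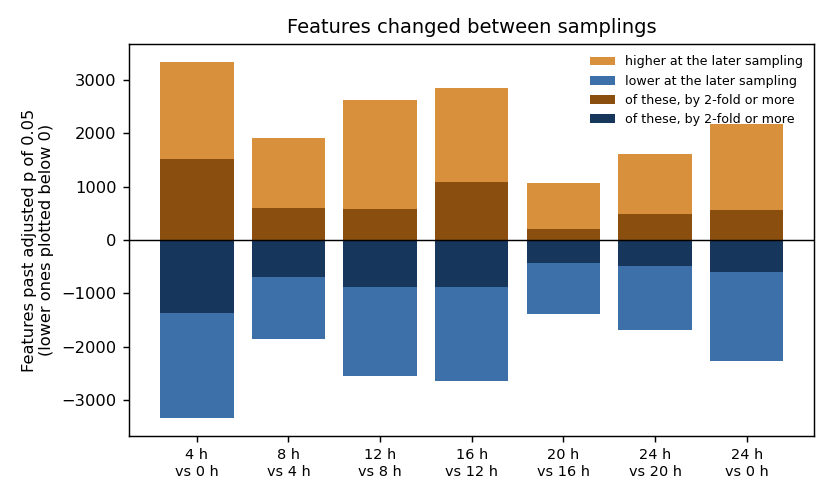
Number of features past an adjusted p of 0.05 (y axis) that were higher (above 0) or lower (below 0) at the later of 2 time points (x axis), by limma over 11168 features. Dark parts of the bars are changes of at least 2-fold; the bars for 4 h against 0 h hold 3339 and 3337 features, those for 20 h against 16 h 1069 and 1380.

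On the deposited scale, features that moved one way between samplings labelled light moved mostly the other way in steps that ended in the dark. Of 3868 features that changed both from 0 h to 4 h and from 12 h to 16 h, 3402 (88%) changed in opposite directions. Those that rose and then fell numbered 1550, where independent lists would share 789, and those that fell and then rose 1852 against 853. Over features the log2 fold changes of both steps had a Pearson r of −0.59 and a Spearman rho of −0.55, features not being independent replicates. These comparisons share no libraries. The reversal was not particular to this pair of steps: the change from 4 h to 8 h was opposite to that from 16 h to 20 h in 91.8% of features changed in both, to that from 20 h to 24 h in 87.1% and to that from 12 h to 16 h in 85.1%. The change from 8 h to 12 h was opposite to that from 16 h to 20 h in 89.9% and to that from 20 h to 24 h in 89.2%, and the change from 0 h to 4 h to that from 16 h to 20 h in 78.2%. From 20 h to 24 h, still labelled dark, 84.1% of 2429 features changed the opposite way to that from 0 h to 4 h, with r = −0.46. The steps from 12 h to 16 h and from 20 h to 24 h went the same way more often, with 28% of 2049 features opposite and r = 0.19. The steps from 0 h to 4 h and from 8 h to 12 h showed little relation, with r = 0.04 and 46.4% of 3202 features opposite. Over 10 pairs of steps without common libraries r ran from −0.59 to 0.19. The 6 successive changes of a feature add up to its 24 h minus 0 h difference, so opposite moves are partly set by a cycle that comes back towards its start. These shares were not recomputed with library totals. That scale made both the step from 0 h to 4 h (5309 higher, 1921 lower) and that from 12 h to 16 h (3529 higher, 2024 lower) mostly rises, so the shares may be lower there.

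After 24 h, levels had come back towards those of 0 h without being the same. The labels place 0 h in the light period and 24 h in the dark period. The mean correlation of 0 h and 24 h libraries was 0.927, above that of 0 h with 4 h (0.830) and with 20 h (0.848). Even so, 4449 features (39.8%) differed, 2181 higher and 2268 lower at 24 h, of which 553 and 604 by at least 2-fold. The 24 h libraries stood as near to those of 20 h, with a mean correlation of 0.928 and 3302 features changed. Row 912 stood at 376 ± 46.8 FPKM at 0 h and 35.1 ± 9.63 at 24 h, a log2 fold change of −3.42 (SE 0.23). Row 565 went from 762 ± 153 to 79.3 ± 38.6 FPKM, or −3.34 (SE 0.31). Row 93 was higher at 24 h, with 226 ± 56.6 FPKM against 11.6 ± 7.65, by 4.42 (SE 0.47). Row 12 stood at 3637 ± 1070 FPKM against 243 ± 147, by 4.14 (SE 0.60). Row 59, among the features that moved furthest in the day, was at 4379 ± 1210 FPKM at 24 h and 3745 ± 307 at 0 h. Library totals as the scale shifted the median feature by 0.17 and gave 3289 higher and 1442 lower.

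Rows 1 and 2 carry labels outside the run of consecutive numbers, and row 3 carries its first number. Row 1, labelled Phatr3_EG02360 and the feature with the most reads over all libraries, fell from 4209 ± 378 FPKM at 0 h through 905 ± 223 at 4 h and 150.5 ± 27.7 at 8 h to 19.6 ± 3.68 at 12 h. It then rose to 487.5 ± 65.6 at 16 h, 778 ± 38.4 at 20 h and 2655 ± 323 at 24 h. Its log2 fold change was −2.88 (SE 0.18) from 8 h to 12 h and 4.58 (SE 0.18) from 12 h to 16 h. Row 2, labelled Phatr3_J46867, had its lowest level of 330 ± 202 FPKM at 12 h and 1925 ± 930 at 16 h, a change of 2.60 (SE 0.40). Row 3, labelled Phatr3_J50604, fell from 1419 ± 61.1 FPKM at 0 h to 659 ± 77.9 at 4 h, or −1.11 (SE 0.15), and stood at 1086 ± 46.4 at 16 h. Light against dark was −1.61 (SE 0.10) for row 1, −1.31 (SE 0.22) for row 2 and −0.77 (SE 0.08) for row 3.

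**Figure D4:**
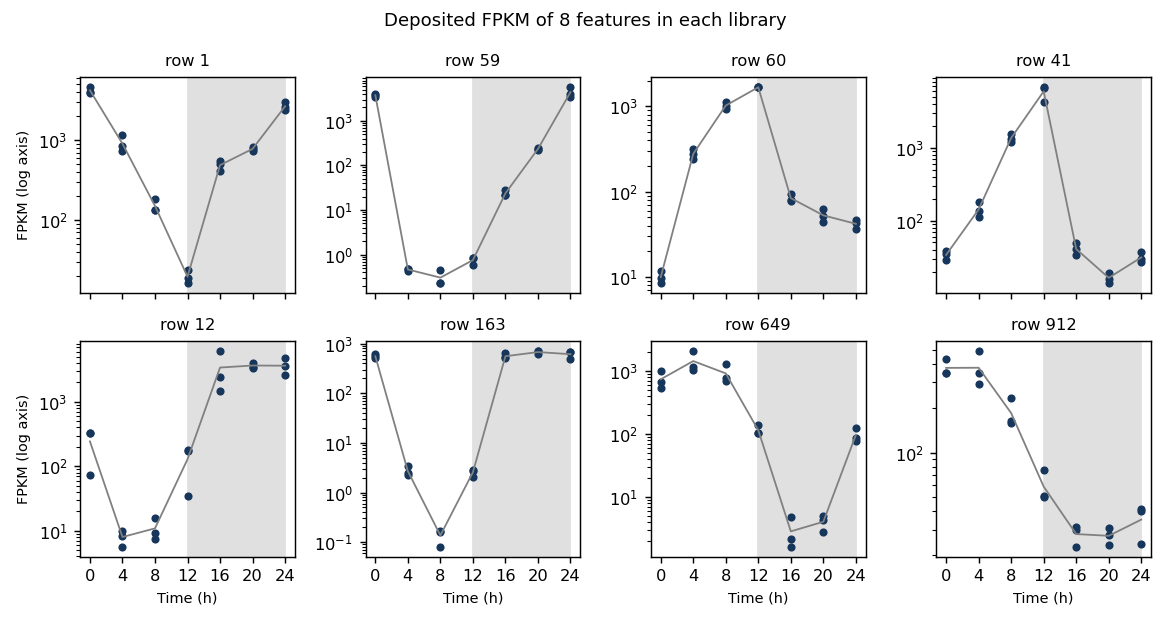
FPKM on a log axis (y axis) against time in h (x axis) for 8 named features. Points are the 21 libraries, lines join the means of 3 libraries and grey marks the dark period; row 59 runs from below 1 FPKM at 4, 8 and 12 h to 4379 ± 1210 at 24 h.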

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

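The library-total scale, voom weights, the length trend, the joint omission of 2 libraries, light against dark without 0 h and 12 h, and quantile normalization for the time of highest level were chosen after seeing the data. Of 115 counts or shares recomputed under settings other than leaving out single libraries, 104 stayed within 1.5 times their value, or within 1 SD for the time of highest level. The counts of features highest at each time point were not among the 115. Library totals moved those at 0, 4 and 20 h by over 1.5 times, to 1390, 2069 and 1365. Keeping only features with a range of at least 2-fold did so at 4, 20 and 24 h, to 679, 364 and 868. Requiring a 2-fold change moved the counts to 1135 for light against dark, 2891 for 4 h against 0 h, 1304 for 8 h against 4 h, 1455 for 12 h against 8 h, 1976 for 16 h against 12 h, 628 for 20 h against 16 h, 972 for 24 h against 20 h and 1157 for 24 h against 0 h, because that setting removes smaller changes. The share of features highest at 0, 12 or 24 h, 62.7%, moved to 44.3% with library totals, 57.8% with quantile normalization and 65.4% among features with a range of at least 2-fold. Library totals divide levels by reads over the scaled total, on average 1.16 at 0 h and 1.06 at 12 h against 0.88 at 4 h and 0.92 at 20 h. That scale therefore lowers 0 h and 12 h and raises 4 h and 20 h. The cause of the other moves was not tested. Leaving out each library in turn gave 9973 to 10342 features changing over time, 6707 to 7108 for light against dark, 6048 to 6902 for 4 h against 0 h, 3083 to 4028 for 8 h against 4 h, 4100 to 5523 for 12 h against 8 h, 4818 to 5780 for 16 h against 12 h, 2449 to 3459 for 24 h against 20 h, 3643 to 4677 for 24 h against 0 h, and 61.8% to 63.9% for the share. For 20 h against 16 h the range was 1606 to 2746, the lowest without library 1 of 20 h. Voom weights on the recovered reads called 10072 features over time. The replicate number as a block gave 10105 features over time and 2461 for 20 h against 16 h and moved no count by over 1.5 times. By the rule that every pair be over 0.1 the numbers did not pair the samples: over 63 pairs of same-numbered libraries the correlation of deviations ran from −0.46 to 0.48, and 25 were over 0.1. The median was 0.04, against −0.02 for other pairs, and 11 of 21 libraries correlated best with their own number, where chance gives 7, a hint from the data that leans towards pairing. Without 0 h the light against dark count was 7751, and with 8 h against 20 h alone 6024, where 5056 of the 6956 calls kept their sign and 58 were called with the other sign. For the features named by the rule, 992 values were recomputed, and all kept their direction and passed the threshold. The rule chose these features from the same data for the largest changes past the threshold. That outcome was therefore largely set by the choice and does not speak for smaller changes. The rows named for their labels were not among the 992 values. The gene list tests, with their own alternatives, were not run, since no row could be assigned to a gene. In simulation, 34.8% of features changed by 0.5 on the log2 scale were called for 4 h against 0 h. Far fewer features were changed there than in the real comparison, so this share does not carry over to it. How many small changes were missed in the real data is not known.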

Other observations

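Tests of the row labels and of 0 h lying nearer the light pattern or further along the night than 24 h, and the values of length by time of highest level and of features confined to a single time were chosen after the results were seen. Features at least 2-fold above every other time point numbered 138 at 0 h and 177 at 12 h, against 52 at 4 h, 18 at 8 h, 3 at 16 h, 0 at 20 h and 10 at 24 h. Counts at 0 h and 24 h are lowered where both were high. Row 3231 had the opposite kind of course, low at 16 h (7.46 ± 3.01 FPKM) and 20 h (6.91 ± 2.50) and between 130 ± 8.67 and 273 ± 76.3 at the other time points. Row 2357 was high at 0 h (582 ± 43.8 FPKM) and 24 h (520 ± 158) and at most 39.2 ± 6.06 at the others.

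Implied feature length differed with the time of highest level. Features highest at 8 h had a median length of 1614 bases and those highest at 20 h 1518, against 1282 over all changed features, and those highest at 0 h 1188 and at 12 h 1203. With each replicate number left out in turn, the medians ran from 1545 to 1674 bases at 8 h, 1442 to 1581 at 20 h, 1086 to 1275 at 0 h, 1140 to 1240 at 12 h and 1137 to 1521 at 24 h. Features are not independent replicates and each library has its own length trend, so no p is given. Below and above the median level, the medians were 1587 and 1674 bases at 8 h, 1524 and 1494 at 20 h, 1231 and 1170 at 12 h, and 1173 and 1197 at 0 h, so 8 h and 20 h stood above the other 2 in both, while the order of 0 h and 12 h changed. Libraries also differed in how level went with length: the slope per doubling of length was −0.096 ± 0.077 on the log2 scale at 0 h, −0.027 ± 0.043 at 4 h, 0.049 ± 0.024 at 8 h, −0.003 ± 0.073 at 12 h, 0.036 ± 0.054 at 16 h, 0.059 ± 0.019 at 20 h and −0.019 ± 0.114 at 24 h (SD, n = 3).

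The row labels form a run of consecutive numbers. If they named the loci in their rows, implied length and RefSeq gene length should be related, but rho was −0.043 over 515 features. A candidate explanation is that the numbers were filled in after the rows had been sorted by reads, since 99.73% of adjacent rows stood in descending order of summed reads. What the true labels were stays open, and rows 2 and 3, with implied lengths of 3116 and 3480 bases for loci of 3279 and 3975, are not excluded. No biological explanation was tested.

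Libraries of the same time point deviated along a shared axis that held 30.8% of the variance within time points, with library 3 of 24 h (0.514) and library 1 of 12 h (−0.405) at its ends. Across features the axis went with implied length (rho = −0.49), so RNA fragmentation or size selection may contribute. Depth did not go with it over the 21 libraries (rho = 0.05, permutation p = 0.88; r = 0.06, p = 0.84; r = 0.08 without the 2 libraries farthest in depth, 100000 permutations within time points). Sampling slightly earlier or later in the day was argued against too, as the median size of r between a library's deviation and the change around its time was 0.1, though library 1 of 8 h (−0.33) and library 3 of 20 h (−0.32), both near the middle of the axis, passed a size of 0.3. No biological explanation was tested, and what set the length trend stays open.

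The 24 h libraries, labelled dark period, differed from those of 0 h, labelled light period, although 1 full cycle lies between them, and whether 0 h was sampled before or after the light came on is not stated. A length-dependent shift was argued against as the whole cause, since 93.8% of the 4449 calls kept their sign and passed after each library's length trend was removed. That 0 h lay further along the night had no sign in the change from 16 h to 20 h, with r = −0.08 (−0.11 to −0.04 without single libraries). This step, in which fewest features moved, cannot speak for the change from 20 h to 24 h. On component 1 libraries moved from 11.71 to 18.58 at 16 h to −23.26 to −18.38 at 20 h. Those of 24 h lay at −66.3 to −59.28, and those of 0 h beyond them at −88.27 to −81.51. Whether 0 h lay further along the night therefore stays open. A candidate explanation is that 0 h cells had already entered the light pattern, since 0 h minus 24 h went with 4 h minus 20 h at r = 0.40 (0.36 to 0.42), in 64.6% of changed features by sign. Other values did not decide this. Libraries of 0 h had lower mean correlations than those of 24 h with 8 h (0.701 against 0.742) and 12 h (0.595 against 0.656). The same held with 16 h (0.779 against 0.845) and 20 h (0.848 against 0.928), so it was not particular to the light period. With 4 h the correlations were nearly equal (0.830 against 0.824). On component 2, libraries of 0 h (−26.26 to −19.14) lay between those of 24 h (8.74 to 12.58) and 4 h (−65.53 to −53.1). The axis along which replicates deviate, fitted on the 4 h to 20 h libraries, went with 24 h minus 0 h at a size of r of 0.31. This lay between the limits set beforehand for and against it, so its part cannot be told. A difference between days or cultures was not tested.

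For features changing over time, 1 of 100 regroupings of the libraries, the real one, gave 10184 features and the highest other 1616. For light against dark 1 of 100 gave 6956 and the highest other 1251. Both sets of regroupings break up the time points, so they show only that libraries of a time point are alike. With libraries kept in their time points, 9 of 35 divisions into 4 and 3 time points, the labelled one included, gave as many as light against dark. The highest other was 8176 for 0, 16, 20 and 24 h against 4, 8 and 12 h. Every other division with as many kept 0 h and 24 h on the same side, whereas the labels separate them. The count therefore does not set the labelled division apart. Time points follow one another in a course, so these divisions cannot measure chance. For pairs of time points 10 splits of 6 libraries are too few for a share under 0.05: the real split alone, 1 of 10, gave 6525 features for 4 h against 0 h, 4559 for 8 h against 4 h, 4873 for 12 h against 8 h, 4953 for 16 h against 12 h, 2273 for 20 h against 16 h, 2514 for 24 h against 20 h and 3165 for 24 h against 0 h, and the highest other split gave 0 in each by limma on those 6 libraries. At an unadjusted p under 0.05 the highest other split gave 334 to 1568 features over the 7 pairs, and the real splits 3869 to 6990. Splits that mix both time points count the difference between them as spread, so few calls could come from them.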
